A study of Homo sapiens with 20 samples.

How the data were processed

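The series measured 3 histone marks by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF7 cells, an established line of oestrogen receptor-positive breast cancer grown in DMEM with fetal bovine serum. H3K4me3 marks active promoters, H3K36me3 marks the bodies of transcribed genes, and H3K27me3 is the repressive mark placed by Polycomb repressive complex 2 (PRC2). Ctr9 is the scaffold subunit of the PAF complex, which travels with RNA polymerase II. Of the 20 samples, 15 carry a peak list: 3 marks in each of 5 conditions, with 1 library per mark and condition. The other 5 samples are input chromatin and were not analysed here.

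Per the labels, the inducible line carries a doxycycline-dependent hairpin against Ctr9 and was compared without drug (Vehicle) and with doxycycline at 500 ng/ml for 7 days (+ Dox). The stable lines carry a scrambled hairpin (shControl) or 1 of 2 hairpins against Ctr9 (shCtr9#3 and shCtr9#5). The contrasts were + Dox against Vehicle, shCtr9#3 against shControl and shCtr9#5 against shControl. shControl against Vehicle, which sets 2 conditions with intact Ctr9 side by side, was computed in the same way. It also holds any difference between the inducible and stable lines. shCtr9#5 against shCtr9#3 was set beside it as another gauge of spread, which holds any difference between the hairpins. Each mark and condition has 1 library, so no contrast has a replicate check, and the 2 hairpins share 1 control library. No sample has doxycycline with a control hairpin, so + Dox against Vehicle also holds any effect of the drug itself. After the data were seen, the log2 peak number and covered length of the 5 libraries of a mark were also fitted with line and knockdown terms, and the knockdown term was set against all 6 exchanges of knockdown and control labels within the lines (exact permutation test, two-sided, 6 tests, not adjusted). This takes + Dox and the 2 hairpins as replicates of 1 knockdown, its p measures only the spread between these libraries, which may be technical, and the smallest p it allows is 0.167, so it cannot reach 0.05. No test was run per gene.

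The deposited files list 1 peak per line with its chromosome, start, end, centre or summit, and the gene and kind of location the authors assigned to it (promoter, exon, intron or distal). Positions are in base pairs, per the file headers, on the hg38 build. Per the submitters' processing notes, Bowtie 1.1.2 and MACS2 2.1.0.20151222 were used. The calling options, the threshold, the use of the input libraries and the source of the authors' gene annotation are not given in the sources used here. Each list belongs to 1 sample. The lists hold no peak height, fold enrichment or significance value and no read totals, so the depth of each library is unknown. A more deeply sequenced or better enriched library yields more and wider peaks, and this difference cannot be removed from such lists. Peak numbers skip a few entries in some lists, for a reason not given in the sources used here.

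Covered lengths, overlaps (at least 1 bp) and covered shares of windows were computed from the peaks as listed, without merging. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and plots were drawn with matplotlib 3.10.9. Chromosomes 1 to 22 and X were used. The retained share is the percent of the control's covered length that the other library of the contrast also covers. Random overlap was taken from 100 shuffles (base seed 1). Each shuffle moved all peaks of a chromosome together by 1 random offset, wrapping at the last peak end, so their spacing and clustering were kept. Shares of peaks carry 95% Wilson intervals, which cover counting error only.

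Gene positions came from the GRCh38.p14 table of 19970 protein-coding genes. Of the 17047 gene names in the peak lists, 16655 (97.7%) matched it. The table gives no strand, so the transcription start site (TSS) of a gene was placed at the end that at least 80% of the authors' promoter peaks within 5 kb of either end pointed to, over all 15 lists. This placed 12474 genes. ESR1, GATA3, TP53 and KRT5 were not placed. A gene with no promoter peak in any list is missing from the TSS counts, so the set of genes depends in part on the peaks compared. H3K4me3 and H3K27me3 were measured as the percent of the window from 5 kb before to 5 kb after the TSS that lies in peaks, and H3K36me3 as the percent of the gene body in the 18723 genes of at least 2 kb. A gene counted as risen or fallen when this share changed by at least 50 percentage points. Counts at 25 and 10 points are given beside it. For H3K27me3, an earlier pass used the whole gene with 5 kb to each side as the main measure. The TSS window, fixed at the outset, was restored after both had been seen, and the whole-gene measure is kept as an alternative chosen after seeing the data.

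There were 17 gene lists: HOX genes, developmental transcription factors, basal and mesenchymal genes, neuronal genes, muscle and liver genes, olfactory receptors, imprinted genes, interferon-response genes, haematopoietic genes, luminal and oestrogen-response genes, ribosomal proteins, cell-cycle genes, PRC2 subunits, PRC1 subunits with demethylases, PAF complex subunits with elongation factors, zinc finger genes of chromosome 19, and clustered protocadherins. 1 listed gene was absent from the table. A list's mean change was placed as a percentile among 10000 random lists of the same size matched on the mean covered share of both libraries, or, as an alternative, on that of the control. The percentile describes these libraries and is not a p-value. Overlaps of genes between the inducible contrast and each hairpin are given beside the value for independent lists. No such overlap is given between the 2 hairpins.

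Genes were named by a rule: per mark, the 10 largest rises and 10 largest falls common to the 3 contrasts, ranked by the weakest change, which had to exceed the difference between the 2 controls, with 1 gene per Mb; by the same ranking and bound the 5 largest in the inducible contrast and the 5 largest common to both hairpins; up to 4 members of each list; and CTR9, EZH2, SUZ12, ESR1 and GATA3. The contrasts, the size rule, the lists, the naming rule and the alternative settings listed next were fixed before the data were examined. These settings were at least 50% of a peak covered, a change of 25 points, peaks under 3 kb apart joined, TSS windows of 2 kb or 10 kb to each side, the 3'-most 50% of the gene body, genes of at least 10 kb, chromosomes 1 to 22, 20 kb in place of 100 kb bins, and random lists matched on the control. Added after seeing the data were peaks of at least 2 kb only, the widest peaks in equal number in each library of a mark, the whole-gene H3K27me3 measure, TSSs placed from the control lists alone, and TSSs placed from the H3K4me3 and H3K36me3 lists alone (11341 genes).

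The code was tested on simulated data. Interval arithmetic was wrong in 0 of 1000 checks. In each mark, gains were added to 200 genes of the shControl list: all 100 genes given 60 points were found at 50 points, and all 100 given 30 points were found at 25 points and 0 at 50 points. Genes at 50 points came to 103 for H3K4me3, 112 for H3K27me3 and 104 for H3K36me3, since neighbouring genes share windows. Of 200 random lists drawn without regard to the added gains, 98.5%, 97.0% and 96.0% lay inside the central 95% range for the 3 marks in the same order.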

Results

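The peak lists describe H3K4me3, H3K27me3 and H3K36me3 in MCF7 breast cancer cells with Ctr9 intact (Vehicle and shControl) or depleted through an inducible hairpin (+ Dox) or 2 stable hairpins (shCtr9#3 and shCtr9#5). The design asks how loss of this PAF complex subunit alters the 3 marks, and in particular the H3K27me3 domains made by PRC2. Each mark and condition has 1 library, so no value carries a replicate error, and each contrast is set beside the difference between the 2 controls, which also differ in line, and its totals beside the difference between the 2 hairpins. Gene values are given as the percent of the window in peaks, in the order Vehicle, + Dox, shControl, shCtr9#3 and shCtr9#5. Read depth is unknown for all 15 libraries. No library has doxycycline with Ctr9 intact, so an effect of the drug cannot be told apart from knockdown in + Dox.

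At the targeted gene, CTR9, the H3K4me3 share of the TSS window was 18%, 23%, 22.3%, 24.4% and 23.4%, and no H3K27me3 peak lay there in any library. H3K36me3 covered 25%, 57.5%, 86.6%, 63.8% and 91.4% of its body. Hairpins act on the transcript, so these marks do not check the knockdown, and the labels stand unchecked. The genes of the PRC2 enzyme EZH2 and its partner SUZ12 likewise held no H3K27me3 in any library, with H3K4me3 at 26.5%, 33.3%, 35.4%, 35.8% and 36.9% for EZH2 and 17.6%, 17.9%, 18.1%, 20.5% and 26.6% for SUZ12.

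H3K27me3 covered more of the genome in each knockdown library than in its control. In the inducible line the TSS windows of 4 genes rose by at least 50 points: CRISPLD2, VASH1, an angiogenesis inhibitor, UMODL1 and the potassium channel subunit gene KCNG1. With the stable hairpins 80 genes rose in shCtr9#3 and 246 in shCtr9#5, and both sets hold OPCML, a cell-adhesion gene, TNC, which encodes the matrix protein tenascin C, and TLR2, a receptor of innate immunity. A single gene fell by 50 points in the inducible line, LILRA2 (an immunoglobulin-like receptor), and 0 fell with either hairpin. Between the 2 controls 0 genes rose and 1 fell, TBX2, a developmental transcription factor, at 67.2% in Vehicle and 3.73% in shControl, named here after its values were seen. Between the hairpins 48 were higher in shCtr9#5 by 50 points and 0 lower. The counts depended on which genes had a placed TSS: with TSSs placed from the H3K4me3 and H3K36me3 lists alone, so that H3K27me3 peaks had no part in the choice, 4, 36 and 127 genes rose and 0 fell, with 0 rises and 1 fall between the controls.

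Peaks numbered 13125 in Vehicle, 29434 in + Dox, 13398 in shControl, 48429 in shCtr9#3 and 61503 in shCtr9#5, and covered 15.1, 34.5, 16.2, 86.9 and 113.3 Mb. The covered length was thus 2.28 times the control's in the inducible line, 5.38 times in shCtr9#3 and 7.01 times in shCtr9#5, against 1.07 times between the controls and 1.30 times between the hairpins (shCtr9#5 against shCtr9#3). Over the 5 libraries together, a test chosen after the data were seen, the knockdown ratio was 4.02 for length and 3.15 for peak number (two-sided exact permutation p = 0.167 for each, the smallest this design allows). The length in peaks of at least 5 kb was 2.61, 15.4 and 22.2 times the control's, and 1.00 times between the controls. Mean peak width was 1152 bp in Vehicle and 1171 bp in + Dox, and 1207, 1795 and 1843 bp in shControl, shCtr9#3 and shCtr9#5. With the widest 13125 peaks of each library, the length ratios were 1.71, 3.44 and 4.12, and with peaks of at least 2 kb 2.45, 8.43 and 11.3. Most peaks were distal or intronic. Promoter peaks made up 6.35% of peaks in Vehicle (95% Wilson interval 5.95 to 6.78), 4.81% in + Dox (4.57 to 5.06), 4.74% in shControl (4.39 to 5.11), 3.38% in shCtr9#3 (3.23 to 3.55) and 4.22% in shCtr9#5 (4.06 to 4.38).

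**Figure D1:**
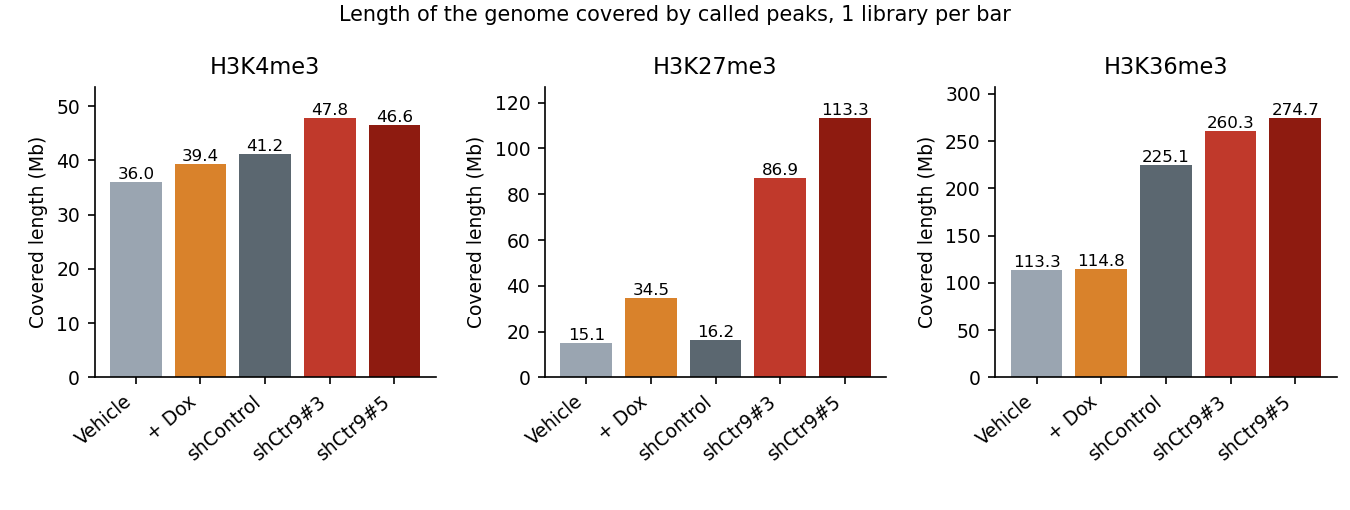
Genome length covered by peaks (Mb, vertical axes from 0) for each mark and library, 1 bar per library. H3K27me3 goes from 15.1 to 34.5 Mb in the inducible line and from 16.2 to 86.9 and 113.3 Mb in the stable lines, while H3K36me3 already differs between the controls, at 113.3 and 225.1 Mb.

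The 10 genes named for the largest common H3K27me3 rise, with 1 per Mb, were CRISPLD2, LAIR1, EGFLAM, BTNL2, CFAP65, EDN3, IGFBP3, WIPF3, FXYD6 and GPNMB. CRISPLD2 (chromosome 16, 84819985 to 84909508) was covered at 29.6%, 85.7%, 20.6%, 73.2% and 84.2%. The inhibitory leukocyte receptor gene LAIR1 (chromosome 19, 54351384 to 54376088) stood at 6.91%, 51.6%, 23.6%, 86.9% and 100%. EDN3, the endothelin 3 gene (chromosome 20, 59300611 to 59325992), stood at 15.3%, 62.1%, 42.4%, 82.0% and 100%. IGFBP3 (chromosome 7, 45912245 to 45921272), a binding protein of insulin-like growth factors, had 0% in Vehicle, 39.5% in + Dox, 26.5% in shControl, 64.8% in shCtr9#3 and 81.0% in shCtr9#5. GPNMB, which encodes a membrane glycoprotein, went the same way at 0%, 37.3%, 18.6%, 73.8% and 69.3%. FXYD6, whose product regulates the sodium pump, was at 33.0%, 70.5%, 32.1%, 89.0% and 100%.

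Among genes ranked on the inducible contrast alone, VASH1 was covered at 8.0%, 60.9%, 0%, 20.8% and 37.8%, and AXIN2, a feedback inhibitor of Wnt signalling, at 0%, 48.4%, 11.3%, 9.06% and 42.6%. UMODL1 stood at 10.5%, 62.1%, 23.5%, 8.73% and 65.6%, and KCNG1 at 19.4%, 70.5%, 12.3%, 10.2% and 46.3%, so for VASH1 the values were above their controls in all 3 contrasts and for AXIN2, UMODL1 and KCNG1 in + Dox and shCtr9#5. Among genes ranked on both stable hairpins, OPCML (chromosome 11, 132414981 to 133532501) stood at 9.11%, 14.6%, 2.84%, 96.0% and 91.5%. TNC (chromosome 9, 115019575 to 115118157) stood at 2.93%, 3.13%, 0%, 100% and 80.5%. TLR2 (chromosome 4, 153684280 to 153710637) was at 0%, 5.67%, 8.86%, 86.4% and 88.2%, PRUNE2 at 0%, 22.9%, 0%, 78.2% and 100%, and the sodium/calcium exchanger gene SLC24A4 at 15.2%, 37.0%, 0%, 77.1% and 100%.

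Of 11 genes lower in all 3 contrasts, 2 had a weakest fall above the difference between the controls, the fatty acid transporter gene SLC27A2 (37.5%, 13.6%, 38.6%, 33.1% and 35.2%) and ARC, an activity-regulated neuronal gene (9.26%, 6.29%, 11.3%, 0% and 4.69%). LILRA2 was covered at 76.5% in Vehicle and 13.4% in + Dox, with 29.2% in shControl, 72.6% in shCtr9#3 and 100% in shCtr9#5. ILDR2 (67.5% and 27.1%), the diacylglycerol kinase gene DGKG (35.8% and 0%), CCNO (38% and 2.97%) and ZDHHC2 (55.1% and 21.3%) were also named on the inducible pair. At each of these genes both hairpins lay above shControl. In shControl, shCtr9#3 and shCtr9#5 ILDR2 stood at 50.8%, 83.8% and 80.5%, and DGKG at 14.4%, 24.2% and 55.05%. CCNO stood at 11.7%, 28.4% and 46.7%, and ZDHHC2 at 37.2%, 100% and 100%. With the hairpins, the phospholipid scramblase gene PLSCR4 went from 20.1% in shControl to 0% and 5.99%, and PNOC, the nociceptin precursor gene, from 11% to 0% in both, with UPK3B (10.1% to 0% in both) and SPR (7.03% to 0% in both). From Vehicle to + Dox, PNOC (18.1% to 21.2%) and UPK3B (5.71% to 7.28%) were higher, and PLSCR4 (6.1% to 0%) and SPR (3.18% to 0%) lower.

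At a change of 25 points, H3K27me3 rose at 126 genes in + Dox, 427 in shCtr9#3 and 883 in shCtr9#5 and fell at 21, 4 and 0, while between the controls it rose at 31 and fell at 57. At 10 points the rises came to 563, 1024 and 1734 and the falls to 233, 50 and 12, with 189 rises and 395 falls between the controls. The mean share over all 12474 windows was 1.41% in Vehicle and 2.14% in + Dox, and 1.02%, 3.28% and 5.56% in the stable lines. Genes with a promoter peak numbered 787 in Vehicle and 1262 in + Dox, and 574, 1441 and 2310 in shControl, shCtr9#3 and shCtr9#5. The number of rises at 50 points moved with the window, to 52, 185 and 534 with 2 kb to each side of the TSS and to 0, 29 and 103 with 10 kb, and the falls to 23, 4 and 0 and to 0 in all 3. Over whole genes the rises were 0, 11 and 72 and the falls 0, a measure chosen after seeing the data.

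HOX genes and developmental transcription factors were among the lists with the most H3K27me3 in the controls, and both had higher means in all 3 knockdown libraries. Of 71 measured developmental transcription factors, 30 were higher and 17 lower in + Dox, 36 higher and 5 lower in shCtr9#3, and 57 higher and 1 lower in shCtr9#5. Among the 46 of them placed without the H3K27me3 lists, 17, 20 and 34 were higher and 12, 4 and 0 lower. Their mean share was 8.57% in Vehicle and 12.8% in + Dox, and 5.03%, 16.5% and 25.9% in the stable lines. NEUROG3, a neurogenic factor, stood at 27.8%, 58.6%, 20.2%, 82.1% and 71.1%, and ASCL1, another, at 19.3%, 16.4%, 0%, 41.6% and 81.9%. The limb and bone factor DLX5 stood at 3.85%, 38%, 19.7%, 46.0% and 72.4%. Among 25 HOX genes, which pattern the body axis, the mean was 10.0% in Vehicle and 13.1% in + Dox, and 6.08%, 14.2% and 24.5% in the stable lines. HOXD13 stood at 20.7%, 27.3%, 10.3%, 55.9% and 82.7%, and HOXB9 at 62.6%, 63.2%, 35.2%, 76.4% and 91.6%.

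Basal and mesenchymal genes, 27 of them measured, averaged 6.51% and 8.55% in the inducible pair and 3.41%, 12.9% and 25.6% in the stable lines, with 12, 12 and 23 members higher than control and 5, 3 and 0 lower (9, 11 and 18 higher and 5, 3 and 0 lower among the 21 placed without the H3K27me3 lists). EGFR, the epidermal growth factor receptor gene, stood at 3.34%, 21.9%, 0%, 42.8% and 55.9%. ZEB2, a driver of epithelial-mesenchymal transition, was at 15.4%, 0%, 0%, 67.8% and 58.0%, and TWIST1, another, at 0%, 0%, 7.89%, 60.5% and 56.8%. The 23 neuronal genes averaged 4.66% and 6.66%, then 4.69%, 13.8% and 27.4%, with the dopamine receptor gene DRD2 at 14.9%, 0%, 12.3%, 30.4% and 94.3%. Of the neuronal genes 12 were placed without the H3K27me3 lists, with 6, 5 and 5 higher and 0 lower. These 12 averaged 4.41% and 9.69% in the inducible pair, then 3.89%, 11.25% and 18.9%. Of 390 olfactory receptors 60 were placed, 57 of them only through the H3K27me3 peaks compared, so their TSS counts are not given. Over whole genes, a measure chosen after seeing the data, 27, 79 and 108 of the 390 were higher than control and 6, 8 and 7 lower. Muscle and liver genes (8 measured, 5 of them placed only through H3K27me3 peaks) averaged 8.90% and 11.8%, then 5.62%, 14.0% and 23.5%, with APOB, the apolipoprotein B gene, at 57.0%, 61.3%, 44.9%, 62.1% and 97.3%.

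Set among random lists matched on both libraries' coverage, the developmental list's mean change lay at percentile 54.6 in + Dox, 51.8 in shCtr9#3 and 29.1 in shCtr9#5. Matched on the control's coverage alone, it lay at 99.9, 99.8 and 100. The HOX list lay at 33.2, 18.9 and 56.7 by the first matching and 88.7, 72.3 and 96.9 by the other. The basal and mesenchymal list lay at 27, 67.6 and 80, against 80.7, 98.8 and 100. How far these lists stood apart from other genes thus depended on the matching. The first matching includes the knockdown library's own coverage. Where the control held little, it therefore matches in part on the change itself and draws the percentile toward the middle. The matching on the control has a limit too. Of the 71 developmental genes 25 were placed only through H3K27me3 peaks, while 11341 of all 12474 genes were placed without them. Such members can raise the percentile, and none was computed without them.

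The other lists held little H3K27me3 in both controls. Means in the order of the 5 conditions were 0.343%, 2.49%, 0.0947%, 0.863% and 3.37% for 30 luminal and oestrogen-response genes, with PGR, the progesterone receptor gene, at 0%, 9.01%, 0%, 11.5% and 29.2%. They were 1.34%, 1.29%, 0.623%, 1.34% and 2.28% for 34 cell-cycle genes, and 1.32%, 0.998%, 0.846%, 0.995% and 1.1% for 48 ribosomal protein genes. Values of 0.0419%, 0.0160%, 0%, 0% and 0.201% were found for 161 zinc finger genes of chromosome 19. The clustered protocadherins (14 measured) were at 0% except in shCtr9#5, at 0.111%. All 10 measured PRC2 genes were at 0% in the 5 libraries, and the 17 PAF complex and elongation genes at 0% except in Vehicle, at 0.265%. PRC1 subunits and demethylases (18) averaged 0.600%, 0%, 1.30%, 0.162% and 2.95%, with RNF2, a catalytic PRC1 subunit gene, at 10.8%, 0%, 23.4%, 0% and 22.1%, and the direction of this list's difference turned under some alternatives in each contrast. Imprinted genes (21) averaged 1.36%, 4.56%, 2.27%, 6.03% and 16.3% (the shCtr9#3 difference turned to -0.121 points with the widest peaks in equal number), interferon-response genes (19) 0.264%, 4.35%, 1.20%, 5.60% and 6.72%, and haematopoietic genes (16) 0.493%, 3.76%, 0.690%, 1.48% and 4.84%. With TSSs placed without the H3K27me3 lists, the haematopoietic difference in shCtr9#3 was -0.345 points, in 10 genes, and the interferon differences were 1.56, 1.59 and 0.409 points, in 15 genes.

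**Figure D2:**
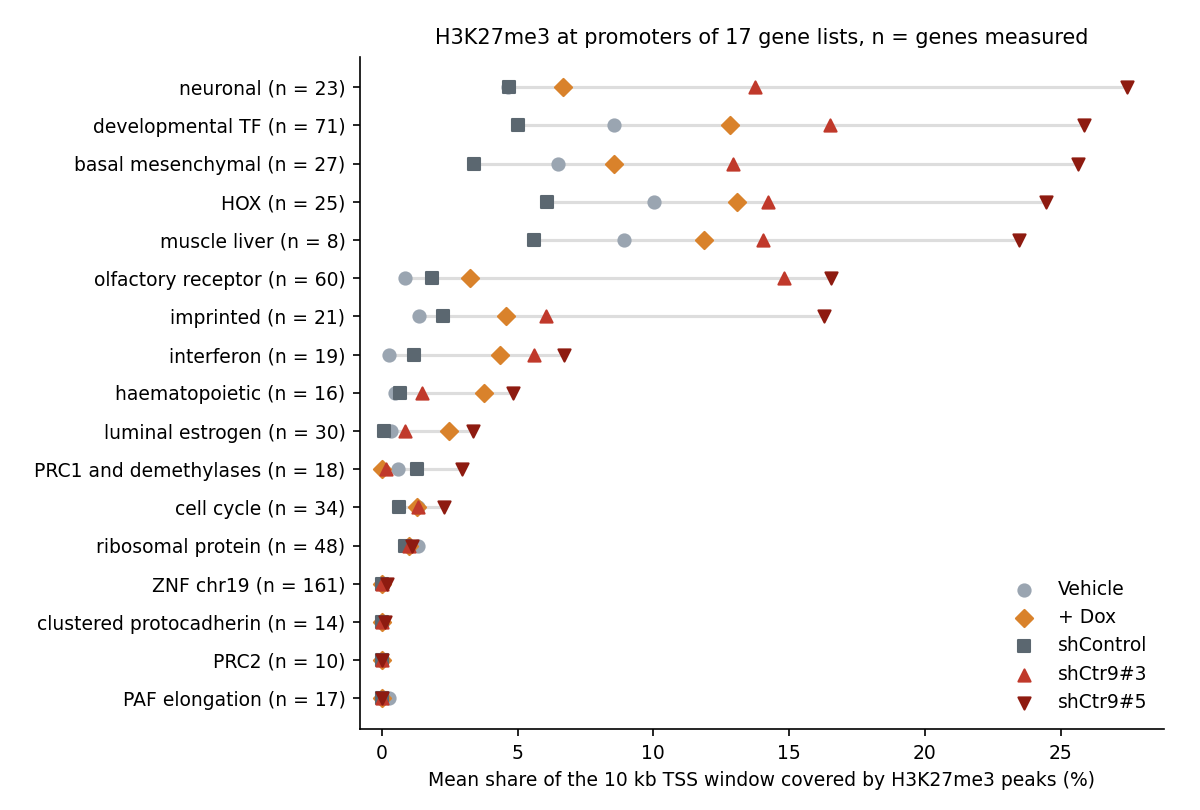
Mean percent of the TSS window covered by H3K27me3 (horizontal axis) for each of the 17 gene lists (vertical axis), with 1 point per library. Some lists hold many genes placed only through the H3K27me3 peaks compared, which can raise their points. These were 57 of 60 olfactory receptors, 5 of 8 muscle and liver genes, 11 of 23 neuronal genes and 25 of 71 developmental transcription factors. The olfactory receptor points should not be read as a result. The developmental transcription factors go from 8.57% to 12.8% in the inducible line and from 5.03% to 16.5% and 25.9% in the stable lines, whereas the PRC2 genes stay at 0%.

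Genes that rose in the inducible line rose in the stable lines more often than independent lists would give. At 25 points, 61 genes were common to + Dox and shCtr9#3, where independent lists give 4.31, and 91 to + Dox and shCtr9#5, where they give 8.92. These contrasts use different control libraries. The value for independent lists counts all 12474 windows, of which 10350, 10606 and 9765 held no H3K27me3 in either library of the contrast. It is thus a low bar, and part of the excess reflects which windows carry the mark at all. The 28.0 Mb gained in + Dox were covered to 46.5% by shCtr9#3 and 57.8% by shCtr9#5, and to 14.2% by shControl, against shuffled means of 3.92%, 5.11% and 0.819%. These shares grow with the length of the covering list. Set against its shuffled mean, the share of shControl, with Ctr9 intact, was no smaller in proportion than those of the hairpins. The control's own H3K27me3 length was retained to 42.6% in + Dox, 69.9% in shCtr9#3 and 78.6% in shCtr9#5. Only 28.5% of the Vehicle length was covered by shControl, which had about the same total.

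**Figure D3:**
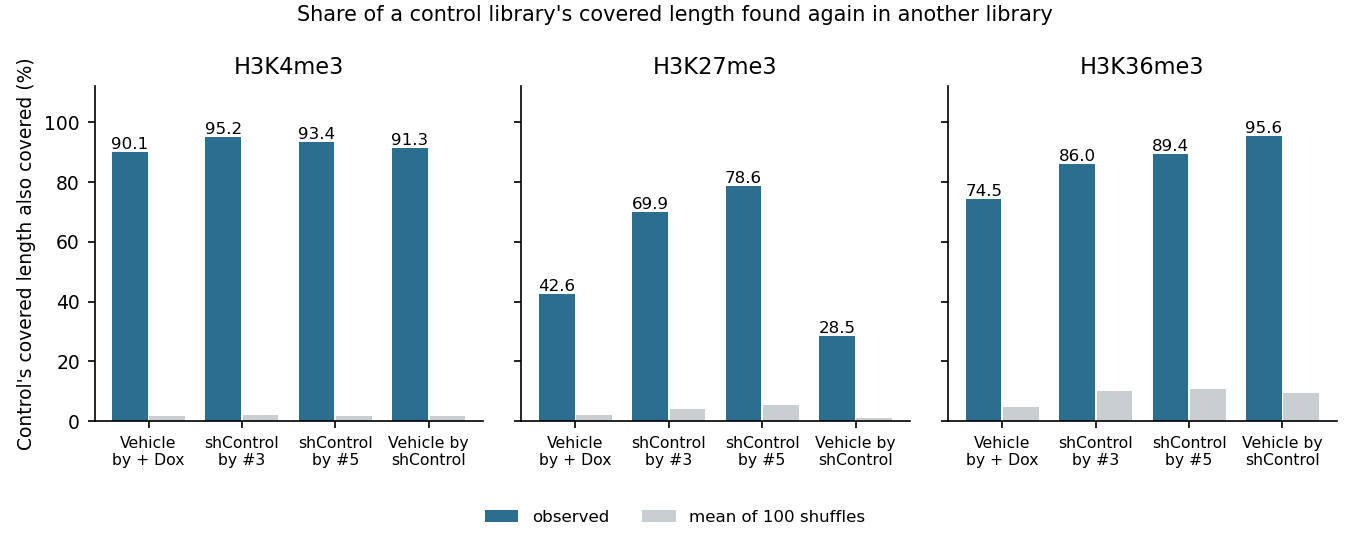
Percent of the reference library's covered length that the other library also covers (vertical axis, from 0) for each mark and contrast as blue bars, with the mean of 100 shuffles as grey bars. H3K27me3 is retained to 42.6%, 69.9% and 78.6% in the 3 knockdown contrasts and to 28.5% between the 2 controls, below H3K4me3, which lies between 90.1% and 95.2%.

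Along the genome, H3K27me3 length was more than 1.5 times the control's on 22 of 23 chromosomes in + Dox, where X stood at 1.49 times, and on all 23 with each hairpin. The ratio was highest on chromosome 3 in + Dox (2.94 times) and on chromosome 18 with shCtr9#3 (10.1 times) and shCtr9#5 (14.1 times). Of 30303 bins of 100 kb, 19 rose by at least 25 points in + Dox, 562 in shCtr9#3 and 933 in shCtr9#5, and 0 fell, while between the controls 0 rose and 2 fell. In 151478 bins of 20 kb, 524, 4283 and 6291 rose by 25 points and 6, 1 and 0 fell, with 73 rises and 58 falls between the controls. The bin at 6700001 to 6800000 on chromosome 10, with the largest rise common to the 3 contrasts, went from 9.88% to 45.0% in the inducible line and from 20.2% to 78.9% and 83% in the stable lines. In the 500 kb around it, from 6500001 to 7000000, which holds part of PRKCQ, the gene of a protein kinase C isoform of T cells, H3K27me3 covered 12.2%, 32%, 17.7%, 68.0% and 70.4%. H3K36me3 had 0 peaks there except for 2 in shControl. On chromosome 20, the bin at 60900001 to 61000000 was covered at 23.4%, 56.7%, 30.9%, 69.6% and 73.9%.

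**Figure D4:**
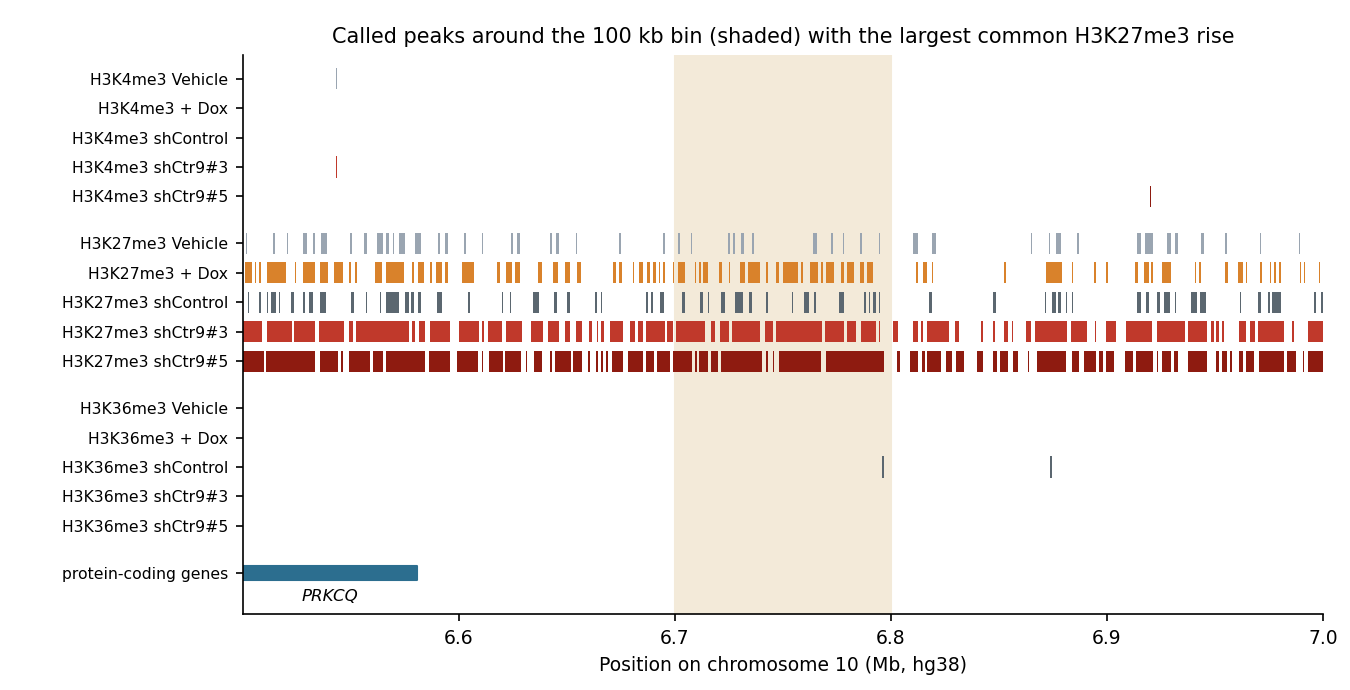
Map of chromosome 10 from 6500001 to 7000000 (hg38, horizontal axis in Mb) with the peaks of each mark as bars in 1 lane per library, the gene PRKCQ beneath and the bin from 6700001 to 6800000 shaded. H3K27me3 peaks cover 12.2% of the region in Vehicle, 32% in + Dox, 17.7% in shControl, 68.0% in shCtr9#3 and 70.4% in shCtr9#5.

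H3K4me3 stayed at nearly the same promoters, and its mean peak width was 1362 bp in Vehicle, 1463 bp in + Dox, and 1400.2, 1474 and 1507 bp in shControl, shCtr9#3 and shCtr9#5. Of genes with a promoter peak in the control, 97.1%, 99.4% and 99.5% kept one in + Dox, shCtr9#3 and shCtr9#5, and 97.8% between the controls. S100P, which encodes a calcium-binding protein (chromosome 4, 6693878 to 6697170), had the largest common difference, at 19.9%, 33.5%, 24.0%, 46.6% and 45.8%. FEM1A stood at 21.3%, 33.2%, 22.6%, 44.8% and 49.3%, the zinc transporter gene SLC39A6 at 53.8%, 68.9%, 62.2%, 81.2% and 73.8%, and the metallothionein gene MT2A at 25.9%, 35.7%, 24.6%, 38.5% and 40.4%. None of the 12474 windows changed by 50 points in any of the 3 contrasts.

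In the inducible pair, EEF1A1, the translation elongation factor gene, went from 50.8% to 79.8% and ATIC, a purine synthesis gene, from 29.0% to 57.6%, while shControl, with Ctr9 intact, held 76.3% at EEF1A1 and 48.0% at ATIC. With both hairpins, C5AR2, a complement receptor gene, stood at 7.94% in shControl, 43.9% in shCtr9#3 and 48.1% in shCtr9#5, CCN5 at 0%, 41.3% and 24.6%, and the receptor kinase gene MST1R at 8.14%, 31.0% and 34%. From Vehicle to + Dox, C5AR2 (15.4% to 13.0%) and MST1R (16.2% to 14.05%) were lower and CCN5 (2.67% to 6.91%) higher. On the falling side were the adrenergic receptor gene ADRB1 (25.6%, 17%, 25.6%, 20.1% and 19.1%), the receptor kinase genes MERTK (22.4%, 18.5%, 22.4%, 17.7% and 19.3%) and AXL (2.60%, 0%, 2.52%, 0% and 0%), and the chemokine gene CXCL3 (3.09%, 0%, 3.93%, 0% and 0%). IL11, a cytokine gene, had 39.9% in Vehicle, 8.02% in + Dox, 17.3% in shControl, 25.8% in shCtr9#3 and 28.5% in shCtr9#5, and the collagen gene COL5A1 39.1%, 14.4%, 14.9%, 34.2% and 36.2%.

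H3K4me3 peaks numbered 26398, 26915, 29450, 32459 and 30917 and covered 36, 39.4, 41.2, 47.8 and 46.6 Mb. The covered length was 1.1 times the control's in + Dox, 1.16 times in shCtr9#3 and 1.13 times in shCtr9#5, 1.15 times between the 2 controls, and 0.973 times between the hairpins. Over the 5 libraries together the knockdown ratio was 1.123 for length (exact permutation p = 0.167) and 1.05 for peak number (exact permutation p = 0.333). At 25 points 12, 3 and 6 genes rose and 3, 0 and 0 fell, against 44 and 1 between the controls and 0 and 1 between the hairpins. The 3 that rose in shCtr9#3 were C5AR2, CCN5 and ANGPTL4 (18.3% to 44.9%), and the 3 that fell in + Dox were IL11, the endothelin-converting enzyme gene ECE1 (51.5% to 23.4%) and the hypoxia-induced carbonic anhydrase gene CA9 (25.1% to 0%), of which ANGPTL4 and CA9 are named after their values were seen. ECE1 stood at 31.0% in shControl, with Ctr9 intact, and higher in shCtr9#3 (49.4%) and shCtr9#5 (42.8%). The fall at CA9 did not exceed the difference between its 2 controls. Rises at 25 points were thus fewer in each contrast than between the controls. With peaks under 3 kb apart joined, rises at 50 points came to 2, 7 and 9, with 2 between the controls.

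Luminal and oestrogen-response genes had higher H3K4me3 in most members: 24 of 30 were higher and 4 lower in + Dox, 22 and 8 in shCtr9#3, and 27 and 3 in shCtr9#5, with means of 41.7% and 47.7%, then 48.8%, 53.9% and 54.4%. Most windows of all genes were higher as well: of 12474, 7644, 9001 and 7873 were higher and 3367, 2073 and 3232 lower. Their mean change lay at percentiles 99.1, 92.7 and 99.3 of matched random lists, and at 97.4 between the controls. TFF3, a trefoil factor gene induced by oestrogen, stood at 4.82%, 8.74%, 0%, 19.3% and 25.4%, and the retinoic acid receptor gene RARA at 8.77%, 8.69%, 8.88%, 25% and 33.0%. Basal and mesenchymal genes went opposite ways: 2 of 27 were higher and 21 lower in + Dox, with means of 16.8% and 13.3%, whereas 20 were higher and 3 lower with each hairpin, from 14.5% to 16.7% and 17%. Between the controls this list went from 16.8% to 14.5%, below all matched random lists (percentile 0). Ribosomal protein genes averaged 35.8% and 43.1%, then 44.3%, 47.0% and 47.8%. PRC2 genes averaged 26.7% and 30.0%, then 30.2%, 34.3% and 34.1%, and PAF complex and elongation genes 29.3% and 34.2%, then 35.0%, 37.5% and 37.0%.

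H3K36me3 differed more between the inducible and the stable line than between knockdown and control. Gene bodies averaged 16.9% in Vehicle and 16.7% in + Dox, and 27.9% in shControl, 32% in shCtr9#3 and 33.3% in shCtr9#5. GPT, an alanine aminotransferase gene (chromosome 8, 144503068 to 144507172), had the largest common difference, at 0%, 43.3%, 38.8%, 100% and 100%. Its promoter peaks totalled 27912 and 29040 bp with the hairpins, far more than its body, so these shares may not be particular to GPT. POLR2K, an RNA polymerase subunit gene, stood at 0%, 32.2%, 18.1%, 45.9% and 53.6%, the glutathione transferase gene GSTK1 at 36.8%, 65.4%, 54.2%, 76.6% and 81.4%, and TRAF6, a signalling adaptor gene, at 20.4%, 44.0%, 34.8%, 53.0% and 79.5%. Lower in all 3 were SELENOM, a selenoprotein gene (35.6%, 0%, 64.6%, 17.3% and 19%), HOXA2 (27.3%, 0%, 45.5%, 0% and 0%) and SUPT4H1, which encodes an elongation factor subunit (87.9%, 70.1%, 87.7%, 81.2% and 81.1%).

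At 50 points 17 bodies rose and 47 fell in + Dox, 74 rose and 1 fell in shCtr9#3, and 52 rose and 1 fell in shCtr9#5, while 425 rose and 0 fell between the controls and 24 and 16 between the hairpins. Among the rises in + Dox were RPS3A (13.2% to 81.6%), POLR1G (0.806% to 65.6%), which encodes an RNA polymerase I subunit, and RPS23 (11.5% to 72.4%), RPS3A and RPS23 being ribosomal protein genes, and shControl held 81.2%, 64.6% and 65.1% there. TNFRSF6B, a decoy receptor gene, went from 100% to 0%, TMEM86B from 100% to 8.14%, PTPRCAP from 100% to 17.1%, PMEPA1, a target of TGF-beta signalling, from 93.6% to 11.9%, and the neuronal enolase gene ENO2 from 79.1% to 0%. None of these fell with the hairpins. In shControl, shCtr9#3 and shCtr9#5 TNFRSF6B stood at 84.2%, 100% and 100%, and PMEPA1 at 51.9%, 95.2% and 82.6%. ENO2 stood at 45.6%, 83.7% and 86.9%, and TMEM86B and PTPRCAP at 100% throughout. Both hairpins covered SAPCD1 and the imprinted gene NNAT at 100%, from 0% and 27.8% in shControl, the macrophage marker gene CD68 at 79.3% and 63.1%, from 0%, and PLAUR, the urokinase receptor gene, at 90.8% and 89.0%, from 26.7%. The inducible pair went the other way at SAPCD1 (17.8% to 1.05%), NNAT (12.1% to 0%) and PLAUR (70.9% to 0%), and CD68 stayed at 0%. Several of these bodies are short beside the peaks over them. SAPCD1 spans only 31762656 to 31764850 on chromosome 6, and its promoter peaks totalled 7006 and 7080 bp with the hairpins. Whether such peaks belong to a neighbouring gene was not tested. The single falls were SERP1 in shCtr9#3 (54.9% to 0%) and NHLRC1 in shCtr9#5 (54.1% to 0%), both named after their values were seen. Over the 3'-most 50% of the body the rises came to 61, 191 and 182 and the falls to 170, 16 and 9, and in genes of at least 10 kb to 2, 21 and 14 and to 26, 0 and 0.

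H3K36me3 peaks numbered 35231, 34784, 62029, 56736 and 51029 and covered 113.3, 114.8, 225.1, 260.3 and 274.7 Mb. Length was 1.01, 1.16 and 1.22 times the control's, 1.99 times between the controls, and 1.06 times between the hairpins. The peak number was 0.987, 0.915 and 0.823 times the control's, and went above 1 when only peaks of at least 2 kb were counted (1.01, 1.06 and 1.01 times). Over the 5 libraries together the knockdown ratio of peak number was 0.917 (exact permutation p = 0.333) and that of length 1.11 (exact permutation p = 0.167). Luminal and oestrogen-response genes averaged 42.5% and 43.2% in the inducible pair and 54.3%, 63.2% and 66.0% in the stable lines, where 27 of 36 members were higher and 7 lower in shCtr9#3 and 30 and 5 in shCtr9#5. Of all 18723 bodies, 9022 were higher and 3145 lower in shCtr9#3, and 9670 and 2314 in shCtr9#5, so most changed bodies rose whatever the list. TFF1, the oestrogen-induced trefoil gene, stood at 7.08%, 6.30%, 26.6%, 80.3% and 90.9%, and AREG, the amphiregulin gene, at 0%, 9.46%, 17.2%, 55.0% and 86.8%. ESR1, the oestrogen receptor gene, was at 5.16%, 25.7%, 36.9%, 41.4% and 57.5%, and GATA3, a luminal transcription factor gene, at 67.6%, 71.1%, 71.6%, 89.7% and 89.5%. Ribosomal protein genes averaged 61.8%, 68.0%, 73.0%, 78.9% and 79.4%, and cell-cycle genes 39.1%, 43.7%, 56.9%, 59.7% and 63.8%, with the shCtr9#3 difference of the latter turning to -0.840 points over the 3'-most 50% of the body.

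Gained H3K27me3 lay almost entirely outside regions that carried H3K36me3 in the control, a mark of transcribed gene bodies. Of the gained length, 1.36% in + Dox, 0.242% in shCtr9#3 and 0.580% in shCtr9#5 lay on the control's H3K36me3, below the lowest of 100 shuffles in each contrast (3.55%, 6.53% and 7.15%). This was not particular to the gain. The controls' own H3K27me3 lay on H3K36me3 to 2.19% in Vehicle (lowest shuffle 3.71%) and 0.897% in shControl (lowest shuffle 6.53%). On the control's H3K4me3 lay 1.80%, 0.557% and 1.39%, with shuffled means of 1.31%, 1.43% and 1.49%. About as much of the gain as not was close to older H3K27me3: 53.9%, 50.7% and 48.2% lay within 10 kb of a control peak, against 9.17%, 8.10% and 8.20% when shuffled. Genes whose H3K27me3 rose by 10 points had H3K36me3 over 6.22%, 3.49% and 5.34% of their bodies in the control, and other genes 22.7%, 38.8% and 40.9%. An H3K4me3 promoter peak was present in the control at 58.1%, 47.5% and 56.2% of the genes with the rise and at 86.3%, 87.8% and 89.0% of the others. Both gaps are in part built in, because a gene was measured only where some list had a promoter peak. Genes without an H3K27me3 promoter peak thus entered only through the other marks. In the same library, 68.2%, 58.9%, 55.4%, 49.3% and 56.1% of the genes with an H3K27me3 promoter peak also had one of H3K4me3.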

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

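Of the tests in this part, the cover of H3K27me3 regions called in Vehicle and missed in shControl, and the setting of peaks of at least 2 kb, were chosen only after the result was seen.

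H3K27me3 covered 2.28, 5.38 and 7.01 times the control's length in + Dox, shCtr9#3 and shCtr9#5. Extra narrow peaks near the calling threshold are argued against as the whole cause, since the length in peaks of at least 5 kb was at least 2.61 times the control's in the 3 contrasts, and copy-number differences of single chromosomes are argued against by a ratio above 1.5 on at least 22 of 23 chromosomes. More sensitive calling in the knockdown libraries (depth, enrichment or input) cannot be told apart from a gain through loss of Ctr9: the lowest retained share of 42.6% met the bound of under 70% set beforehand against it, but that bound was wrong, because shControl, of like length and with Ctr9 intact, covers only 28.5% of the Vehicle length, and Vehicle 26.6% of the shControl length. Regions called in Vehicle and missed in shControl were covered again to 45.7% by shCtr9#3 and 61.6% by shCtr9#5, above every shuffle (highest 6.84%), so a part of the gain over shControl may lie where control cells already had the mark. The part seen in this way is 6.53% of the gained length in shCtr9#3 and 6.62% in shCtr9#5. It is capped, since these regions hold 10.8 Mb and the gains 75.6 and 100.6 Mb. Vehicle may have missed marked regions too, so the part may be larger, and the rest, an effect of Ctr9 loss included, stays open. In + Dox an effect of doxycycline itself stays open as well, since no library has the drug with Ctr9 intact.

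H3K36me3 covered 225.1 Mb in shControl and 113.3 Mb in Vehicle, both with Ctr9 intact, and the stable knockdown libraries covered more still. More sensitive calling in the stable libraries could account for this, since shControl covered 95.6% of the Vehicle length, as a more complete list of the same regions would. A difference between the inducible and the stable line stays open beside it, because the libraries of a line may share depth or handling. The H3K27me3 lengths of the same 2 controls, 15.1 and 16.2 Mb, did not part in this way.

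Gained H3K27me3 lay outside regions with H3K36me3 in the control. Random placement of the gained regions is argued against: at most 1.36% of the gained length lay on the control's H3K36me3 in the 3 contrasts, where the lowest of the shuffles for that contrast (+ Dox) was 3.55%. The controls' own H3K27me3 also lay there less than in any shuffle, at 2.19% in Vehicle and 0.897% in shControl. The placement is thus not particular to the gain. Weak H3K27me3 that control cells already held outside transcribed genes, and that a more sensitive library would show, stays open, because 53.9%, 50.7% and 48.2% of the gain lay within 10 kb of a control peak.

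Several values moved one way in the inducible contrast and the other way with both stable hairpins. None of these differences between the lines was tested. The share of H3K4me3 peaks that were distal changed by -0.347 points in + Dox and by 1.63 and 1.37 points in shCtr9#3 and shCtr9#5. Mean H3K4me3 of basal and mesenchymal genes changed by -3.55 points in + Dox and by 2.20 and 2.51 points with the hairpins, and shControl lay below Vehicle for this list. For imprinted genes the H3K4me3 changes were -1.34, 2.58 and 2.34 points, and for neuronal genes -1.63, 1.20 and 1.58 points. With peaks of at least 2 kb the neuronal value in shCtr9#5 was -0.548 points, the same direction as in + Dox.

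In H3K36me3, the share of promoter peaks changed by -0.0527 points in + Dox and by 0.786 and 0.938 points with the hairpins, and the share of distal peaks by 0.342, -1.27 and -1.83 points. Mean H3K36me3 over all gene bodies changed by -0.273, 4.10 and 5.37 points, and by 10.96 points between the controls (shControl against Vehicle). The changes were -3.29, 6.62 and 10.5 points for PRC1 subunits and demethylases, and -1.05, 2.05 and 1.42 points for developmental transcription factors, where shCtr9#5 turned to -0.278 points over the 3'-most 50% of the body. They were -4.01, 5.76 and 3.70 points for interferon-response genes, and -1.87, 2.22 and 2.41 points for neuronal genes. In genes of at least 10 kb the interferon values turned to 0.599 points in + Dox and -0.471 points in shCtr9#3.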

How the results depend on the processing

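Chosen after the data were seen were peaks of at least 2 kb only, the widest peaks in equal number, the H3K27me3 measure over whole genes, and TSSs placed from the control lists alone or from the H3K4me3 and H3K36me3 lists alone. Values are in the order + Dox, shCtr9#3, shCtr9#5 and, after "controls", shControl against Vehicle, and the cause of a move was not tested unless given. Of 1313 alternative values, 938 stayed (within 1.5 times, their counting interval or, for list means, 1 point, and for percentiles still inside or outside the central 95% range), 356 moved and 19 reversed. A list mean counted as reversed only where its main change was at least 1 point; of smaller ones another 24 values changed sign, 9 of them counted as moved and 15 as unmoved. Stricter significance, a fold enrichment threshold and equal numbers of the strongest peaks were not run, since the lists hold no strength, and no contrast could lose a library, with 1 on each side. The unknown depth limits all of these values, as no setting can even it out. Chromosomes 1 to 22 alone moved none of the 24 peak number and length ratios beyond 1.5 times, and TSSs from the control lists none of the 8 H3K27me3 gene counts (rises at 4, 62 and 187). With TSSs from the H3K4me3 and H3K36me3 lists H3K27me3 rose at 36 and 127 genes with the hairpins and fell at 0 in + Dox, and 9 of 51 list means moved. With 20 kb bins, of which there are more, H3K27me3 rose by 25 points in 524, 4283 and 6291 (controls 73) and fell in 6, 1 and 0 (controls 58), while the ratio of bins with any rise to bins with any fall stayed within 1.5 times in the 9 knockdown contrasts of the 3 marks. The H3K27me3 length ratio was above 1.5 in the 3 knockdown contrasts under each alternative run for it.

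With at least 50% of a peak covered, which can only lower the share, the control's peaks were met to 84.4%, 90.6% and 88.1% for H3K4me3 (controls 86.4%), 31.4%, 60.4% and 70.6% for H3K27me3 (controls 18.5%) and 60.1%, 68.4% and 72% for H3K36me3 (controls 92.3%). With the widest peaks in equal number they were met to 86.2%, 91.4% and 90.6% (controls 86.9%), 34.5%, 53.0% and 58.4%, and 74.4%, 85.7% and 89.9% (controls 89.4%). The H3K27me3 length ratio was then 3.44 for shCtr9#3 and 4.12 for shCtr9#5, H3K27me3 fell at 3 genes in + Dox, and H3K36me3 rose at 131 and 126 genes with the hairpins and fell at 8 and 3 (controls 3).

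A change of 25 points, which can only raise the counts, gave H3K4me3 rises at 12, 3 and 6 genes (controls 44) and falls at 3 in + Dox (controls 1). It gave H3K27me3 rises at 126, 427 and 883 (controls 31) and falls at 21, 4 and 0 (controls 57), and H3K36me3 rises at 254, 781 and 918 (controls 3342) and falls at 447, 59 and 33 (controls 19). Joining peaks under 3 kb apart gave H3K4me3 rises at 2, 7 and 9 (controls 2, and 2 falls), H3K27me3 rises at 65, 201 and 465 (controls 7) and falls at 8, 1 and 0 (controls 17), and H3K36me3 rises at 46, 183 and 149 (controls 1037) and falls at 128, 13 and 18 (controls 1).

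Peaks of at least 2 kb only gave H3K4me3 rises at 13, 4 and 8 genes (controls 16), H3K27me3 length ratios of 8.43 and 11.3 and peak ratios of 6.68 and 8.56 with the hairpins, and H3K27me3 rises at 11 and falls at 6 genes in + Dox (controls 3 and 2). For H3K36me3 the peak ratio reversed from 0.987, 0.915 and 0.823 to 1.01, 1.06 and 1.01, rises came to 65, 196 and 205 (controls 765) and falls to 108, 17 and 3 (controls 9). Windows of 2 kb to each side gave H3K4me3 falls at 2 genes in + Dox and rises at 2 with each hairpin (controls 5 rises and 2 falls), and H3K27me3 rises at 52, 185 and 534 (controls 12) and falls at 23, 4 and 0 (controls 46). Windows of 10 kb gave H3K27me3 rises at 0, 29 and 103 and falls at 0 in + Dox (controls 2). Over whole genes H3K27me3 rose at 0, 11 and 72 and fell at 0 in + Dox. The 3'-most 50% of the body gave H3K36me3 rises at 61, 191 and 182 (controls 805) and falls at 170, 16 and 9 (controls 7), and genes of at least 10 kb gave rises at 2, 21 and 14 and falls at 26, 0 and 0, from fewer genes.

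List means of at least 1 point that reversed, in points, were for H3K4me3 the PRC1 subunits and demethylases in shCtr9#5 with joined peaks (-0.129, from 2.68), and with peaks of at least 2 kb the interferon genes in shCtr9#3 (-0.558, from 1.36) and the neuronal genes in shCtr9#5 (-0.548, from 1.58). For H3K27me3 they were the PRC1 subunits and demethylases in shCtr9#3 over whole genes (0.489, from -1.14) and in shCtr9#5 with peaks of at least 2 kb (-1.14), the widest peaks (-1.30) and 2 kb windows (-0.988), from 1.65, and the imprinted genes in shCtr9#3 with the widest peaks (-0.121, from 3.77). For H3K36me3 over the 3'-most 50% in shCtr9#3 they were the PAF complex and elongation genes (-1.96, from 2.37), PRC2 (-0.433, from 5.47) and cell-cycle genes (-0.840, from 2.74). In shCtr9#5 they were the clustered protocadherins with joined peaks (-0.651) and over the 3'-most 50% (-0.347), from 2.13, and developmental transcription factors over the 3'-most 50% (-0.278, from 1.42). In genes of at least 10 kb the interferon genes turned in + Dox (0.599, from -4.01) and in shCtr9#3 (-0.471, from 5.76). Of the percentiles, 33 moved when lists were matched on the control alone and 120 did not.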

Other observations

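No test was run on the values in this part, and the genes and regions outside the naming rule were chosen after their values were seen, as was the measure over whole genes.

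Over whole genes with 5 kb to each side, where no TSS is needed, H3K27me3 covered on average 0.142%, 0.542%, 0.337%, 2.58% and 3.30% of the 390 olfactory receptor genes in the order Vehicle, + Dox, shControl, shCtr9#3 and shCtr9#5. Of these genes 27 were higher and 6 lower in + Dox, 79 and 8 in shCtr9#3, and 108 and 7 in shCtr9#5, and the remaining 357, 303 and 275 showed no difference. Neuronal genes (36) averaged 2.37%, 4.15%, 2.95%, 9.51% and 12.4% by this measure. The 53 clustered protocadherins, cell-adhesion genes of neurons, stayed at 0% except in shCtr9#5, at 0.0164%, while H3K36me3 covered 0.884%, 1.16%, 13.3%, 17.7% and 15.5% of their bodies. The protocadherin gene PCDHGC4 stood at 2.61%, 4.91%, 58.4%, 78.2% and 63.4% in H3K36me3. Zinc finger genes of chromosome 19 averaged 18.6%, 20.2%, 38.5%, 45.3% and 45.0% in H3K36me3.

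Some immune, neuronal and luminal genes were among those with a large difference in H3K36me3. HLA-A, a class I antigen-presenting gene, stood at 0%, 0%, 18.2%, 69.5% and 49.4%, and IRF7, an interferon regulatory factor gene, at 53.7%, 27.9%, 37.4%, 87.1% and 89.3%. GAD1, which makes the transmitter GABA, was at 39.6%, 1.28%, 32.1%, 73.5% and 73.4%, and the neuronal tubulin gene TUBB3 at 29.5%, 0%, 9.91%, 44.0% and 51.6%. AGR2, a secretory gene of luminal cells, was at 23.1%, 17.7%, 25.7%, 58.3% and 69.0%.

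Among 100 kb bins with a large H3K27me3 difference in all 3 contrasts, that at 86700001 to 86800000 on chromosome 16 was covered at 19.5%, 51.2%, 29.3%, 65.9% and 78.3%, and that at 72200001 to 72300000 on chromosome 7 at 13.6%, 45.0%, 15.1%, 61.8% and 75.9%. With shCtr9#3 the 4 genes whose H3K27me3 fell by 25 points were CA4 (25.1% in shControl and 0% in shCtr9#3), CACNG7 (44.6% and 19%), IL36G (35.5% and 7.90%) and SFMBT2 (45.8% and 20.8%), and shCtr9#5 held 37.0%, 42.9%, 30.5% and 88.8% at them.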
